A study of soil metagenome with 3 samples.

How the data were processed

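Messenger RNA from soil adhering to potato roots was sequenced in 3 libraries, 1 each from emergence at day 20 after planting, hilling at day 50 and flower advent at day 90. Per the labels' protocols, the root-adhering soil was frozen in liquid nitrogen, RNA was extracted with bead lysis, prokaryotic mRNA was enriched, tailed with poly(A) and amplified with T7 RNA polymerase, and Illumina libraries were made. The series design names 3 plants per stage as biological replicates, but 1 library per stage was given here, and whether it pools plants is not given in the sources used here.

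Each deposited file lists protein entries of UniProt with a description, domain, phylum and order and a read count, per the file headers. The counts deposited by the authors are whole numbers of at least 1 per entry, are not scaled to library size, and sum to a different total in each file. The search tool, the database release, the similarity limit and the number of reads searched are not given in the sources used here. The total in a file is therefore the number of counts on the listed entries, not the sequencing depth, and no count could be scaled to a library. The files give no alignment identity, length or e-value, so the quality of single assignments was not analysed.

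Counts of different entries were not independent. Among 2970 entries filed under Bacteria at flower advent, after leaving out 26 environmental sample entries described as subunit A, or as ammonia monooxygenase with no subunit named, that had at least 25 counts at hilling, 1150 (38.7%, 95% exact Clopper-Pearson interval 37.0% to 40.5%) held exactly 8 counts. A Poisson count, whatever its mean, can place at most 14.0% of entries at that value. The pair of 5 counts at hilling and 8 at flower advent was held by 400 entries, against at most 237 entries on any pair in 100 simulations in which entries drew reads independently. Sums over entries are for this reason given as sums of counts and not as numbers of reads. The count of the highest entry in a group is the fewest reads that can lie behind that group, if a read is counted at most once per entry. Intervals on sums and shares treat each count as a separate read and are too narrow. Intervals on single entries (95%, exact Poisson for a count, Clopper-Pearson on the split of the summed count for a ratio) cover counting error only, and copies made during amplification are not independent molecules. With 1 library per stage there was no spread between replicates, so no difference between stages was tested against such a spread. The tests in the closing section that compare libraries cover counting error only. A count of 0 was given the upper limit of 3 counts per library.

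Libraries were grouped by the growth stage in the labels. Entries were matched to lists of words fixed before the data were examined, searched in the description, domain, phylum and order: ammonia-oxidizing archaea, ammonia-oxidizing bacteria, complete ammonia oxidizers (comammox), methanotrophs, other nitrogen cycle genes, plant names and ribosomal RNA. The files give no genus, so the bacterial list could match only on the order Nitrosomonadales and on the description. The entries named were, by a rule fixed at the same time, the 10 with the highest count in each library, every entry of the emergence library, and the 10 with the largest and the 10 with the smallest ratio of flower advent over hilling by share of the library total, among the 5404 entries with at least 20 counts summed over both libraries, with a pseudocount of 1 for ranking. Other entries named were chosen after their values were seen, and are marked so. Overlap was also taken after thinning to the smaller total in 100 draws. Alternatives covered a minimum of 10 counts per entry, a pseudocount of 0.1, scaling to the median ratio, the highest entry in place of sums, and other ways to divide archaea from bacteria. The minimum of 10 was set on the count of an entry summed over the libraries.

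Values were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0, and plots were drawn with matplotlib 3.10.9. The steps were tested on simulated data. With counts drawn for 8404 entries from the means of the hilling and flower advent libraries and 200 entries changed 4-fold, 91 of the 100 raised and 90 of the 100 lowered entries were among the 100 most extreme ratios in their direction, and 95.9% of the ratio intervals held the true value. The simulated counts were independent Poisson draws without amplification copies, so the intervals were not tested for counts that share reads or hold copies.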

Results

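Transcripts assigned to ammonia monooxygenase, the enzyme that oxidizes ammonia in the first step of nitrification, were counted in rhizosphere soil of yellow potato (Solanum phureja) at 3 growth stages. The gene amoA codes for its subunit A and is the usual marker of ammonia-oxidizing archaea and bacteria. Each stage was represented by 1 library. The emergence library, from day 20 after planting, listed 5 protein entries with 11 counts in total. The hilling library, from day 50, listed 7786 entries with 184805 counts, and the flower advent library, from day 90, listed 8251 entries with 398960 counts. The number of sequenced reads behind these totals was not given in the sources used here, and the counts of similar entries were not independent, so that the highest single entry is given beside each total. That entry held 3 counts at emergence, 96 at hilling (exact Poisson 95% interval 77.8 to 117) and 252 at flower advent (222 to 285).

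The first comparison addressed how the listed entries differed between emergence and the later stages. At emergence, no archaeal entry and no entry described as subunit A was listed. All 11 counts lay on Proteobacteria. Burkholderiales, an order of soil and plant-associated bacteria, held 7 counts on 3 entries described as ammonia monooxygenase with no subunit named. These were V9S690 with 3 counts and T1XGF6 and J1ER87 with 2 counts each. No emergence entry matched the fixed words for ammonia-oxidizing archaea or bacteria. Whether these Burkholderiales entries code for the enzyme that oxidizes ammonia was not tested. The remaining 4 counts lay on 2 entries described as other proteins. F2KE39, filed under Pseudomonadales and described as the chromosomal replication initiator protein, which starts DNA replication, held 3 counts, and I0A715, filed under Enterobacteriales and described as the flavoprotein MioC, held 1.

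Most counts of the later libraries lay on archaeal entries. Of the counts at hilling, 173925 (94.1%) lay on 5246 archaeal entries, against 0 of 11 counts at emergence. A value of 0 of 11 allows a share of up to 27.3% by the limit of 3 counts and 28.5% by the exact interval. Both limits take the 11 counts as separate reads, and would be higher if some of them share reads or are copies. Since counts of similar entries are not independent, the archaeal share of reads at hilling is not known as closely. It would be 0.875% if only the 96 counts of the highest archaeal entry, and every count outside the archaea, were separate reads. The highest archaeal entry at hilling, H6V8W9, held 96 counts, 32-fold the limit of 3 counts at emergence. The highest at flower advent held 252 counts, 84-fold that limit. These folds are not scaled to sequencing depth and do not allow for counting error. The exact Poisson upper limit of 0 counts is 3.69. V9S690 held 3, 1 and 1 counts at emergence, hilling and flower advent, T1XGF6 and J1ER87 each held 2, 0 and 1, I0A715 held 1, 3 and 0, and F2KE39 held 3, 54 and 19. Summed over all Burkholderiales entries, the counts were 7 at emergence, 1 at hilling and 5 at flower advent. These sums were 63.6% of the counts at emergence (exact interval 30.8% to 89.1%), 0.000541% at hilling (up to 0.00301%) and 0.00125% at flower advent (up to 0.00292%). The highest Burkholderiales entry held 3 counts at emergence (exact Poisson interval 0.619 to 8.77) and 1 at hilling (0.0253 to 5.57).

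**Figure D1:**
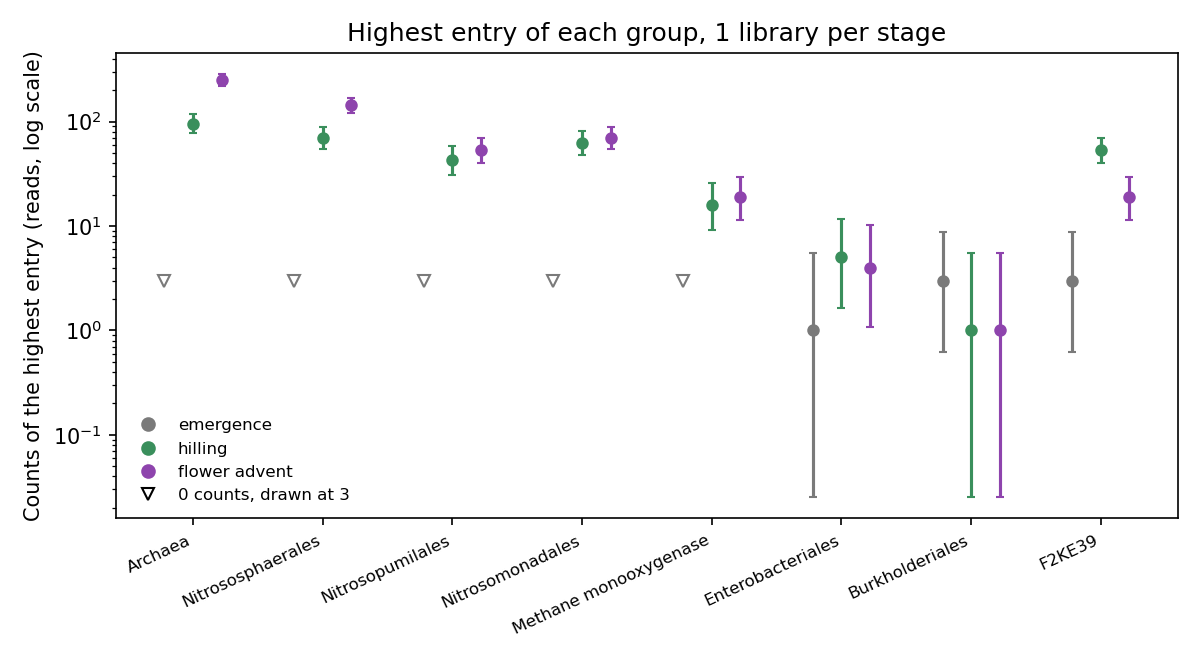
Counts of the highest entry (reads, log scale) in archaea as a whole, in named orders, in entries described as methane monooxygenase and in the entry F2KE39, for the emergence, hilling and flower advent libraries; bars are exact Poisson 95% intervals and open triangles mark 0 counts, drawn at the limit of 3. Archaea had 0, 96 and 252 counts, Burkholderiales 3, 1 and 1, and the highest Nitrosomonadales entry, a subunit C, had 63 at hilling and 70 at flower advent.

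The second comparison addressed which ammonia oxidizers were represented at hilling and at flower advent. Archaea made up 94.1% of the counts at both stages, with 375326 counts on 5250 entries at flower advent. Entries filed under Bacteria made up 5.87% (5.76% to 5.98%) at hilling and 5.91% (5.84% to 5.99%) at flower advent. The archaeal entries were nearly all listed at both stages, 5243 of 5253. Within the archaea, entries filed as environmental samples held 41.6% of all counts at hilling and 45.7% at flower advent, those filed under Crenarchaeota 38.0% and 37.4%, and those filed under Thaumarchaeota 14.5% and 11.0%. These are the names under which the entries were filed, and whether they separate different lineages was not tested. An order was given for 8 archaeal entries, all chosen for mention after their values were seen. The 3 Nitrososphaerales entries, an order typical of soils, held 189 counts at hilling and 353 at flower advent. The 5 Nitrosopumilales entries, an order known from marine waters, held 147 and 174.

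By the fixed list of words, ammonia-oxidizing bacteria were the entries of Nitrosomonadales, the order of Nitrosomonas and Nitrosospira. They held 290 counts on 62 entries at hilling (0.157% of all counts) and 734 counts on 80 entries at flower advent (0.184%). The archaeal share of both lists together was 99.8% at each stage. These lists set every archaeal entry against the bacterial order Nitrosomonadales only. Because the archaeal list took in far more database entries than the bacterial list, the shares also depended on the number of entries. When only the highest subunit A entry of each list was counted, archaea held 96 of 102 counts at hilling (94.1%, exact interval 87.6% to 97.8%) and 252 of 273 at flower advent (92.3%, 88.5% to 95.2%), and these intervals overlapped. When the highest entry of any subunit was counted, the bacterial side was the subunit C entry P95403 and archaea held 60.4% (52.3% to 68.0%) at hilling and 78.3% (73.4% to 82.6%) at flower advent. Both comparisons leave out bacterial entries outside Nitrosomonadales. Over all entries filed under Bacteria, the highest subunit A count was 70 at hilling and 178 at flower advent. The entries with these counts are among the 26 described in the closing section. The words for complete ammonia oxidizers, other nitrogen cycle genes, plant names and ribosomal RNA matched 0 entries in every library, and entries without a genus name could not be matched to a genus. The nitrogen cycle words were gene symbols, so spelled-out descriptions, such as those of subunits B and C and nitrite reductase, were not matched. Entries matching no list held 10373 counts at hilling and 22698 at flower advent, and were mostly bacterial environmental samples. All bacterial entries described as subunit A held 7537 counts at hilling (4.08%) and 16635 at flower advent (4.17%). Nitrosomonadales held 143 and 451 of these. Most bacterial counts described as subunit A thus lay outside the list of ammonia-oxidizing bacteria. Whether they come from ammonia oxidizers was not tested.

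Counts per entry were higher at flower advent than at hilling for 3976 archaeal entries, lower for 1123 and equal for 154. The median archaeal ratio was 1.49 (quartiles 1.03 and 2.81), and the ratio of the library totals was 2.16. Both are ratios of counts not scaled to sequencing depth. The 10 highest entries at flower advent were all archaeal. B3UYT5, D7RNC9, D7RPD6, G8GSV2 and G8GSV8 each held 252 counts, W8Q5L7 held 251, B5LRX4 and I6WJC9 held 250, R9Z375 held 249 and X4QL72 held 248, and their counts at hilling ran from 49 for I6WJC9 and R9Z375 to 57 for D7RPD6, G8GSV2, W8Q5L7 and B5LRX4. B3UYT5 had a ratio of 4.67 (exact interval 3.47 to 6.38). The 10 highest entries at hilling were other archaeal entries with smaller ratios. Picking 1 set by its flower advent count and the other by its hilling count favours this difference by itself. H6V8W9 went from 96 to 160 counts (ratio 1.67, 1.29 to 2.17), V9Q4U0 from 90 to 143, B3UYW6 from 89 to 139, I6TRE6 from 87 to 168, R9YZY0 from 87 to 162, Q0QMD0 from 86 to 138, V9Q6N4 from 86 to 160, W8DYY2 from 86 to 135, W5S8N8 from 85 to 185 and E5G9T0 from 83 to 172.

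**Figure D2:**
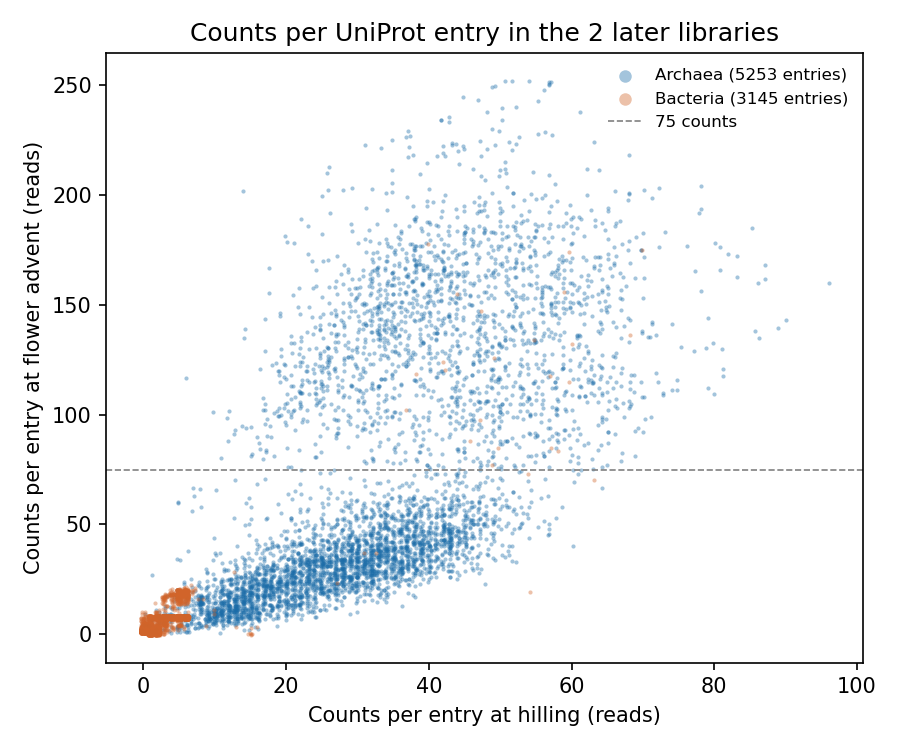
Counts per UniProt entry at hilling (x axis, reads) against flower advent (y axis, reads), with archaeal entries in blue and bacterial entries in orange, each point shifted by under 1 count so that equal values can be seen; the dashed line marks 75 counts. The archaeal entries form a lower band with a median of 30 counts at flower advent and an upper cloud with a median of 138, and most bacterial entries lie near the origin.

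The largest ratios relative to the library totals were all on archaeal entries. A9Q2F3 held 6 counts at hilling and 117 at flower advent, a share 9.03 times as large (exact interval 4.03 to 25.1). C3UWB3 went from 14 to 202 counts, C3UWC3 from 14 to 139, B6S443 from 14 to 135, C3UWC2 from 20 to 181, E3VKW4 from 18 to 167, E3VKE3 from 10 to 101, A9Q2G4 and A9Q6F1 from 5 to 60 each, and C4TNT9 from 1 to 27. Of the 10 smallest ratios, 9 were on archaeal entries and 1 was F2KE39, the replication initiator entry, which went from 54 to 19 counts (share ratio 0.163, 0.0912 to 0.279). G8GRB2 went from 19 to 4 counts (share ratio 0.0975, 0.0241 to 0.293), F8ULQ3 from 36 to 13, G8GRH2 from 30 to 10, H9U112 from 29 to 9, G8GRG6 and G8GS71 from 24 to 8 each, G8GS80 from 22 to 7, G8GRH9 from 20 to 6 and A2TJR5 from 15 to 5. These entries are the extremes of 5404 ranked by this ratio, and their intervals do not allow for that choice. Few entries filed under Bacteria could reach the minimum of 20 summed counts, since 2578 of the 2996 listed at flower advent held 8 or fewer. The number of archaeal entries among the extremes is therefore not a result about archaea. The minimum also left out entries such as Q2HXY1 and A8SIY9, with 15 counts at hilling and 0 at flower advent.

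The Nitrosomonadales entries described as subunit A had a median of 3 counts at hilling and 8 at flower advent. The highest of them, P96951, held 6 and 21 counts (ratio of counts 3.50, exact interval 1.37 to 10.6; share ratio 1.62, 0.633 to 4.91). Entries of the same order for the other subunits were P95403, a subunit C with 63 and 70 counts (ratio 1.11, 0.779 to 1.59; share ratio 0.515, 0.361 to 0.735), O85721, a further subunit C with 13 and 28 counts, and O31189, a subunit B with 10 and 9 counts. These 4 were chosen after their values were seen. The 13 Enterobacteriales entries described as ammonia monooxygenase held 50 counts at hilling and 41 at flower advent, and 9 of them had exactly 5 and 4 counts. The 8 entries described as nitrite reductase, outside the fixed words, held 0 counts at hilling and 11 at flower advent, with at most 3 on any entry.

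The list of methanotrophs, which carry the related particulate methane monooxygenase, matched 61 entries by description, 28 of them described for both enzymes. It held 232 counts at hilling (0.126% of all counts) and 252 at flower advent (0.0632%). Some of its entries are filed under Nitrosomonadales and are also in the list of ammonia-oxidizing bacteria. Without them, 58 entries held 217 counts at hilling and 202 at flower advent. Members of the full list went both ways, with 37 entries higher, 17 lower and 7 equal at flower advent. The 28 described for both enzymes were all higher. Of the 33 described for methane monooxygenase without ammonia, 9 were higher, 17 lower and 7 equal, with a sum of 203 counts at hilling and 112 at flower advent. The highest count among these 33 was 16 at each stage, but on different entries, and the median ratio over the 26 listed at both stages was 1. The 7 entries with at least 15 counts at hilling, among them Q2HXY1 and A8SIY9 with 15 counts each, held 15 to 16 counts there and 0 to 3 at flower advent, and 5 of them were at 0. These 7 were chosen after their values were seen.

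**Figure D3:**
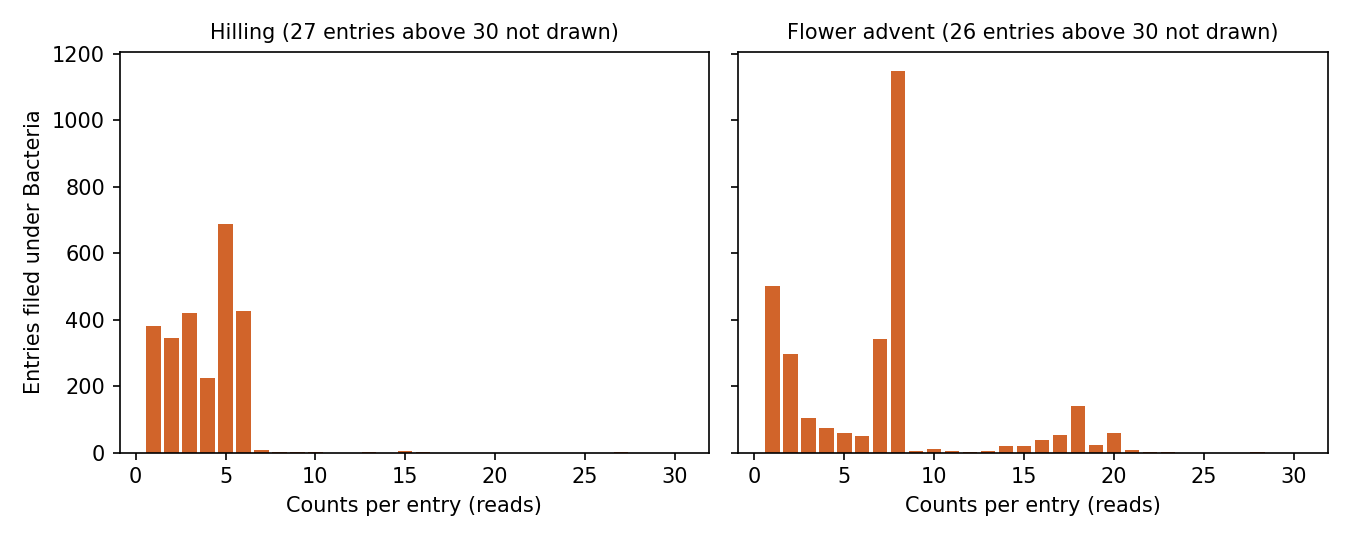
Number of entries filed under Bacteria (y axis) by the counts per entry (x axis, reads) in the hilling library (left) and the flower advent library (right). At flower advent 1150 entries held exactly 8 counts, and 30 entries held 9 to 13.

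The libraries at hilling and flower advent shared 7633 of 8404 entries (Jaccard index 0.908). Among bacterial entries 2385 of 3145 were shared, with 611 listed at flower advent alone and 149 at hilling alone. The counts were correlated across entries, which are not independent replicates, with Pearson's r of 0.893 on log2(count + 1) and Spearman's rho of 0.905. Within archaea Pearson's r was 0.749 and Spearman's rho 0.732, and within bacteria they were 0.753 and 0.750. With 1 library per stage and no total of sequenced reads, differences between the stages were not separated from differences between single libraries.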

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

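The tests of this part were chosen after the results were seen. F2KE39, an entry filed under Pseudomonadales and described as the chromosomal replication initiator protein, is outside the ammonia monooxygenase measurement and held 54 counts at hilling and 19 at flower advent, above the limit of 3 that a count of 0 allows. It held 3 counts at emergence. No control library was among the samples.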

How the results depend on the processing

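No paired analysis was possible because each stage has 1 library, and no replicate could be left out. The highest-entry, subunit A, domain and archaeal-like alternatives were chosen after seeing the data. The totals depended on what was summed. With a minimum of 10 counts per entry, summed over the libraries, they were 3, 183468 and 395736 at emergence, hilling and flower advent. The 3 counts left at emergence were those of F2KE39, the replication initiator entry. With subunit A descriptions only they were 0, 154746 and 331054, and the highest entry held 3, 96 and 252. The ratio of totals over emergence was 16800 at hilling and 36269 at flower advent as summed, 61156 and 131912 with the minimum of 10, and 32 and 84 by the highest entry. The ratios with the minimum of 10 divide by the counts of F2KE39 alone, which is not described as ammonia monooxygenase. The summed ratios divide by 11 counts, among them 3 on F2KE39 and 1 on the flavoprotein entry I0A715. The highest emergence entries, V9S690 and F2KE39 with 3 counts each, were bacterial and not described as subunit A. None of these ratios over emergence is therefore a ratio of subunit A counts. The ratio of flower advent over hilling stayed above 1 in every alternative run, at 2.16 with the minimum of 10, 2.63 by the highest entry of each library and 1.49 as the median over archaeal entries. The highest entries of the 2 libraries were different entries. The archaeal share of both lists at hilling and flower advent was 94.1% and 94.1% with unassigned entries kept, 94.1% and 94.1% against all entries filed under Bacteria, and 60.4% and 78.3% by the highest entry, where the bacterial entry was the subunit C P95403; with the minimum of 10 it was 99.8% at both. The percent filed under Archaea was 94.7% and 94.8% with the minimum of 10 and 94.8% and 94.8% without the archaeal-like bacterial entries. The Jaccard index was 0.999 with the minimum of 10, 0.998 for archaea, 0.758 for bacteria and 0.914 after thinning. Pearson's r was 0.832 with the minimum of 10, 0.831 with a pseudocount of 0.1, 0.871 over entries in both libraries, 0.749 in archaea and 0.753 in bacteria. Scaling to the median ratio of 1.60 in place of the ratio of totals, 2.16, raised every log2 ratio by 0.43. The alternatives of 1 best hit per read, a stricter similarity, correction for entry length and scaling by a stated library total were not run, since the tables used here hold none of these. For any group listed at 0, the 11 counts of the emergence library allowed shares of up to 27.3% by the limit of 3 counts. By the exact interval they allowed 28.5%. Both limits take the 11 counts as separate reads and are too low if they are not. Of the 2996 bacterial entries listed at flower advent, 2578 held 8 or fewer counts.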

Other observations

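All tests in this part were chosen after the results were seen. The archaeal entries fell into 2 sets at flower advent. The 1958 entries with more than 75 counts there had a median of 44 counts at hilling and 138 at flower advent, and the other 3295 entries had medians of 26 and 30. The sets are split on the flower advent count itself. The upper set took in 47.9% of the archaeal entries filed as environmental samples, 33.6% of those filed under Crenarchaeota and 143 of the 795 filed under Thaumarchaeota. Entries with like identifiers tended to be in the same set. Of 79 blocks of at least 20 archaeal entries that share the first 3 characters of their identifier, 41 had at most 10% or at least 90% of their entries in the upper set, against at most 1 block in 100 shuffles.

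A fixed property of each entry, such as its length, combined with a difference in depth would give 1 common ratio. The SD of log2 flower advent over hilling across 4863 entries was 0.90, against at most 0.39 in 100 simulations with 1 ratio and counting noise. The simulations were first taken as the bound for this explanation, but they leave out noise between amplified libraries, which no replicate measures here, so it stays open. With no limit set on the flower advent count, a mixture of 2 normal distributions was favoured over 1 in each hilling range from 11 to 60 counts, but 1 was favoured for 61 to 70 and for 71 to 100. The 2 modes lay 88.2 counts apart for entries with 11 to 20 counts at hilling, 97.0 for 21 to 30, 103 for 31 to 40, 92.7 for 41 to 50 and 71.2 for 51 to 60. From 11 to 20 up to 41 to 50 the distance changed 1.05 times, while the median hilling count rose 2.81 times. With 51 to 60 as the last range these were 0.807 and 3.44 times, but there the fitted lower mode, 78.4, lies above the median of 54 of the lower set, so that the 0.807 does not measure the distance between the 2 sets and nothing is rested on it. A block of about the same number of reads, matched by some entries and not by others, stays a hypothesis, and may be copies of reads from one part of the gene or transcripts of archaeal lineages more abundant at flower advent. These cannot be told apart without read positions and replicate libraries: the highest Nitrososphaerales entry had a ratio of 2.04 (exact interval 1.52 to 2.76) and the highest Nitrosopumilales entry 1.26 (0.826 to 1.92).

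The tables argue against a shallower library alone as the whole cause of the emergence composition, if the counts are separate reads. Whether a shallower library gave the absence of archaeal counts was not decided. The highest entry in each of archaea, every bacterial order, the bacteria with no order and all other entries was compared between libraries by a permutation test of equal composition with 100000 permutations, which covers counting error only. The permutation test gave p = 2e-05 against hilling and 1e-05 against flower advent, and 1e-05 against either with the later counts summed, where 1e-05 is the smallest value possible. It rests on 7 emergence counts, covers all groups at once and does not test the archaea alone. Of the 7 counts, 3 lay on the highest Burkholderiales entry, and the highest of that order at hilling held 1. Another 3 lay on F2KE39 and 1 on I0A715, which are not described as ammonia monooxygenase. The composition tested is thus that of all listed entries, not of ammonia monooxygenase entries alone. The permutation test was the third form of test run on the question. The first used entries chosen by their emergence counts and was dropped. The second asked only for the chance of 0 archaeal counts among 11, which was 2.9e-14 at the archaeal share of 94.1% of summed counts but 0.908 at the lowest share the hilling table allows, 0.875%, and did not decide. Few molecules copied many times during amplification stay open. With 1 count per group at emergence, 3 in all, p was 0.0108 against hilling, but the later counts may be copies too and read positions are not in the tables used here. A biological difference stays open as well, since 3 counts would be 27.3% of the 11 emergence counts and no other emergence library was analysed here.

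Among entries filed under Bacteria, 26 had at least 25 counts at hilling and were described as subunit A or as ammonia monooxygenase, where the other bacterial environmental samples had at most 10. Of these 26, 19 have identifiers that begin with S4V, 4 with U3M and 3 with F8ST, and together they held 11.8% of the bacterial counts at hilling and 12.3% at flower advent. Examples are S4VJR7 with 70 and 175 counts and S4VGV4 with 40 and 178. A candidate explanation is that archaeal sequences were filed under Bacteria, but the counts do not decide it. The 26 entries, chosen by hilling count and description, had a median of 118 counts at flower advent, and the middle 50% of archaeal entries with like hilling counts ran from 40 to 143. A bacterial ammonia oxidizer with reads of its own would also come to lie there, since the median ratio of 2.00 of the other bacterial environmental samples, near the 2.14 of these 26, predicts 98 counts. The entry sequences were not used here.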
